A study of Mus musculus with 7 samples.

How the data were processed

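Total RNA from the palatal shelves of 7 mouse embryos at E13.75 was measured, with 3 wild-type and 4 Adamts9+/-;bt/bt embryos and 1 array per embryo. The series' design text describes the samples as separate embryos, so they are biological replicates. Per the labels' protocols, RNA was extracted with an RNeasy kit and was converted to biotin-labelled cRNA with the Illumina TotalPrep kit. Each sample's deposited file holds linear probe intensity, positive and not normalized between arrays, as its values show. The scanner software and any background step are not given in the sources used here. The authors' value table of the whole series holds log2 values of the same arrays as deposited. Its columns share a median of 6.07, and within each array its ranks equal those of the intensity (Spearman 1), so it is a log2 table normalized between arrays, with a method not given in the sources used here. The smallest intensity was 34.7 and no detection p was used here.

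The 25695 probe IDs held 18116 distinct rows of intensity over the 7 arrays, since most genes with several probe IDs repeat a single value on each of them. Distinct rows were therefore used as features, an adaptation of the planned test per probe made once the values were seen, and 4910 features were read by 2 or more probe IDs. Names came from the platform annotation, in which 23976 probe IDs have 1 gene symbol, 0 have several and 1719 have none. Gene IDs of 23960 probe IDs matched the GRCm38 gene table, and 0 symbols needed updating. Of the features 16876 have 1 gene, 15 join probe IDs of several genes and 1225 have no gene, and only the first kind was named. No genome build is stated for the arrays, so positions from the GRCm38 table served only to find genes that neighbour Adamts9 and Adamts20, and none are printed. Among 144 genes with 2 or more detected features, 4 (Atg2a, Edem2, Mars1 and Zfp787) had features past the threshold in opposite directions.

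Intensities were background-corrected with normexp (offset 50), put on the log2 scale and quantile-normalized between arrays. A feature counted as detected when its mean log2 value lay above the 40th percentile, a limit of 6.10, which left 10869 features of 10087 genes. Mutant and wild type were compared with limma (lmFit and eBayes, 2 groups, no covariate, two-sided), with Benjamini-Hochberg adjustment over all detected features and a threshold of 0.05. Differences are mutant minus wild type in log2 units with limma's SE. Group values are means ± SD. For single genes an exact two-sided permutation test over the 35 splits into 3 and 4 arrays is given, whose smallest p is 0.0286. R 4.3.3 and limma 3.58.1 were used.

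Lists of genes were fixed before the data were examined, for the cell cycle, CDK inhibitors and growth arrest, apoptosis, versican and hyaluronan matrix, the ADAMTS family, other matrix proteases, interstitial matrix, basement membrane, palate transcription factors, TGF-beta and BMP, hedgehog, WNT, and FGF and PDGF signalling, stress, hypoxia and glycolysis, and markers of epithelium, muscle, neurons, glia, melanocytes, red cells, endothelium, leukocytes, cartilage, bone and sex. Each list with at least 5 detected genes was tested with camera at a preset inter-gene correlation of 0.01 on 1 feature per gene (the highest mean), adjusted over the 24 lists tested. The neuron, cell cycle and basement membrane lists passed, and 0 lists passed with an estimated correlation. The alternative set test was limma's fry, which tests whether a list moves 1 way against no change, adjusted over the same lists. Calls of list members were adjusted over all features, and beside that over the list alone. The rule for named genes, also fixed before the data were examined, took Adamts9, Adamts20 and Vcan, Adamts1, Adamts4, Adamts5 and Adamts15 as values, and in each direction the 12 genes with the largest absolute log2 difference among features past the threshold whose mutant values all lie on 1 side of the wild-type values, leaving out clone-named genes. From each list it took up to 6 members past the threshold over all features or over the list alone, by smallest p, or otherwise the 2 members with the smallest p. The text gives some of these, and list members named outside that rule were chosen after their values were seen. They are Tubb3, Scg2, Ncam1, Ccne2 and Melk. Genes near Adamts9 and Adamts20 were counted within 20 Mb with two-sided Fisher's exact tests over 10082 genes with a position. These were adjusted over both loci, separately for calls in either direction, rises and falls.

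The fit was tested on simulated data built on the 10869 detected features of this comparison. It recovered 95.5% of features changed by 0.5 log2 units, 100% of those changed by 1 and 98.5% of those changed by 2, with 5.31% false among 207 calls. A shift of -0.3 simulated in the 46 detected cell cycle genes was found with a median of -0.30, and 0 of 24 lists passed with no simulated change. The simulated genes varied independently, without the correlation among list genes estimated in the data (0.651 for the neuron list). No difference of scale between arrays was simulated either. Both groups were given the same spread, and far fewer features were changed than passed in the data. The simulation therefore does not show how the tests behave under such correlation, scale differences, unequal spread or widespread change. Alternatives fixed beforehand changed the background correction, the normalization between arrays, the source of the values, the detection filter (none, or the 60th percentile), the variance model, array weights, the threshold, the fold minimum, the set test, the feature per gene, the window around the loci, the replicates included, the replicate number as a block and the sex of the embryo as a covariate. A block for the array chip was not run because no chip is named in the sources used here. Alternatives added after the data were seen kept all probe IDs as separate rows, used wild-type replicate 3 as the only wild-type array, and added the mean of the neuron list as a covariate.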

Results

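Palatal shelves, the paired outgrowths that rise and fuse to form the roof of the mouth, were profiled from 7 mouse embryos at E13.75. Of these embryos, 3 were wild type and 4 were Adamts9+/-;bt/bt, in which 1 copy of Adamts9 is missing and both copies of Adamts20 carry the belted (bt) allele. ADAMTS9 and ADAMTS20 are secreted metalloproteases that cleave versican, a large chondroitin sulfate proteoglycan of embryonic matrix. The series asks how this cleavage bears on palatal closure and on proliferation of the palatal mesenchyme. Each embryo was read on 1 Illumina expression array, and the number of arrays limits the precision of every value. The upper quartile of raw intensity was 232.3 ± 20.2 in the wild-type arrays (SD, n = 3) and 184 ± 11.8 in the mutant arrays (SD, n = 4). The exact two-sided permutation p of 0.0286 is the smallest that 35 splits of 7 arrays can give. Mean raw intensity was 354.6 ± 28.2 in wild type and 297.2 ± 19.8 in the mutants (exact permutation p = 0.0857). There the groups overlapped, with wild-type replicate 3 at 322.3 and mutant replicate 1 at 323.4. After normalization, Pearson correlations across detected features (features are not independent replicates) ran from 0.993 to 0.994 among the mutant arrays, from 0.982 to 0.993 among the wild-type arrays and from 0.948 to 0.977 between the groups. The leading principal component held 74.4% of the variance. On it wild-type replicates 1 and 2 lay at -24.4 and -30.8, the mutant arrays lay between 14.9 and 20.3, and wild-type replicate 3 lay between them at -13.0. By Xist and Y-linked genes the wild-type group held 1 female, replicate 3, and 2 males. The mutant group held 2 females, replicates 1 and 3, and 2 males.

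The genes that the genotype and the title name were read first. Adamts9 has no probe in the annotation used here and was not analysed here. Adamts20 was below the detection limit, at 5.98 ± 0.07 log2 units in wild type (SD, n = 3) and 5.99 ± 0.04 in the mutants (SD, n = 4) against a limit of 6.10. Neither targeted gene therefore gave a check of the genotypes. Its values were 5.93, 6.06 and 5.94 in the wild-type arrays and 6.05, 5.96, 6.00 and 5.95 in the mutant arrays (log2 difference 0.01, SE 0.05, 95% interval -0.11 to 0.13, exact permutation p = 0.714). Vcan, which encodes versican, was dim, with a wild-type mean of 6.08 under the detection limit, so the size of its difference depends on the floor. It read slightly higher in the mutants, at 6.27, 6.32, 6.39 and 6.28 against 6.06, 6.00 and 6.18 in wild type. The log2 difference was 0.23 (SE 0.06, 95% interval 0.09 to 0.38, adjusted p = 0.0199, exact permutation p = 0.0286). The Vcan call was lost without wild-type replicate 1 (0.22, adjusted p = 0.0698), without wild-type replicate 2 (0.19, adjusted p = 0.0773), without mutant replicate 3 (0.21, adjusted p = 0.0545) and with wild-type replicate 3 as the only wild-type array (0.13, adjusted p = 0.372). It was also lost with the replicate number as a block. With the mean of the neuron list as a covariate, the Vcan difference was -0.01 (adjusted p = 0.994). That covariate separates the groups without overlap, so this value does not decide whether Vcan differs with genotype. Among other proteases known to cleave versican, Adamts15 fell by 0.30 on the log2 scale (SE 0.08, adjusted p = 0.0185) and Adamts1 rose by 0.25 (SE 0.07, adjusted p = 0.0246), from a wild-type mean of 6.16 near the detection limit. Adamts4 differed by -0.29 (SE 0.10, adjusted p = 0.0513) and Adamts5 by -0.08 (SE 0.08, adjusted p = 0.489), and neither passed the threshold.

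Of the 24 gene lists tested, neuron markers were higher in the mutant shelves and cell cycle and basement membrane genes were lower. These 3 shifts passed with the preset inter-gene correlation and 0 lists passed with an estimated correlation. The largest rises included the neuronal genes Gal, a neuropeptide (9.15-fold, log2 difference 3.19, SE 0.39, adjusted p = 0.000391), and Sncg, a synuclein (7.05-fold, SE 0.39, adjusted p = 0.00077). Further ones were Prph, the peripheral neuron intermediate filament peripherin (7.04-fold, SE 0.41, adjusted p = 0.00101), and Cplx1, a regulator of synaptic vesicle fusion (5.71-fold). Slc17a6, a vesicular glutamate transporter, was 5.60-fold higher. Other large rises were in genes that most cells express. Eef2, a translation elongation factor, read 10.44 ± 0.06 in 4 mutants against 6.18 ± 0.14 in 3 wild types (SD, log2 difference 4.26, adjusted p = 1.66e-08). The chromatin protein Rbbp7 (log2 difference 3.11), the serine synthesis enzyme Phgdh (9.26 against 6.26) and the RNA-binding proteins Hnrnpa2b1 (2.79) and Snrnp70 (2.62) were also higher, as were Tsc22d1 (3.13) and Vstm2l (5.48-fold). In wild-type replicates 1 and 2, Eef2, Tsc22d1, Rbbp7, Phgdh, Hnrnpa2b1 and Snrnp70 lay between 6.06 and 6.77, close to the detection limit of 6.10, so the sizes of their differences depend on the floor and on the background offset. Wild-type replicate 3 read 8.19 for Snrnp70, 8.03 for Rbbp7, 7.95 for Hnrnpa2b1 and 7.30 for Tsc22d1, between the other wild-type arrays and the mutant means of 9.43, 10.06, 9.93 and 9.74. For Eef2 and Phgdh it read 6.34 and 6.52, close to the other wild-type arrays.

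The largest falls were smaller. Chst2, a sulfotransferase that acts on N-acetylglucosamine (3.40-fold lower, log2 difference -1.76, SE 0.16, adjusted p = 0.000124), Col6a2, a chain of collagen VI (3.37-fold lower, SE 0.27, adjusted p = 0.00124), and Pdgfrb, the PDGF receptor of perivascular cells and other mesenchyme (3.25-fold lower, SE 0.13, adjusted p = 6.81e-05), were among them. Others were the Polycomb gene Cbx2 (3.25-fold lower), the histone methyltransferase gene Kmt2b (3.07-fold lower), Tmem131 (3.30-fold lower), Prrc2a (3.03-fold lower), the cartilage collagen Col2a1 (2.98-fold lower), the actin-bundling gene Fscn1 (2.86-fold lower), Ptpru (2.80-fold lower), the Hippo pathway transcription factor Tead2 (2.71-fold lower) and Vat1 (2.69-fold lower).

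**Figure D1:**
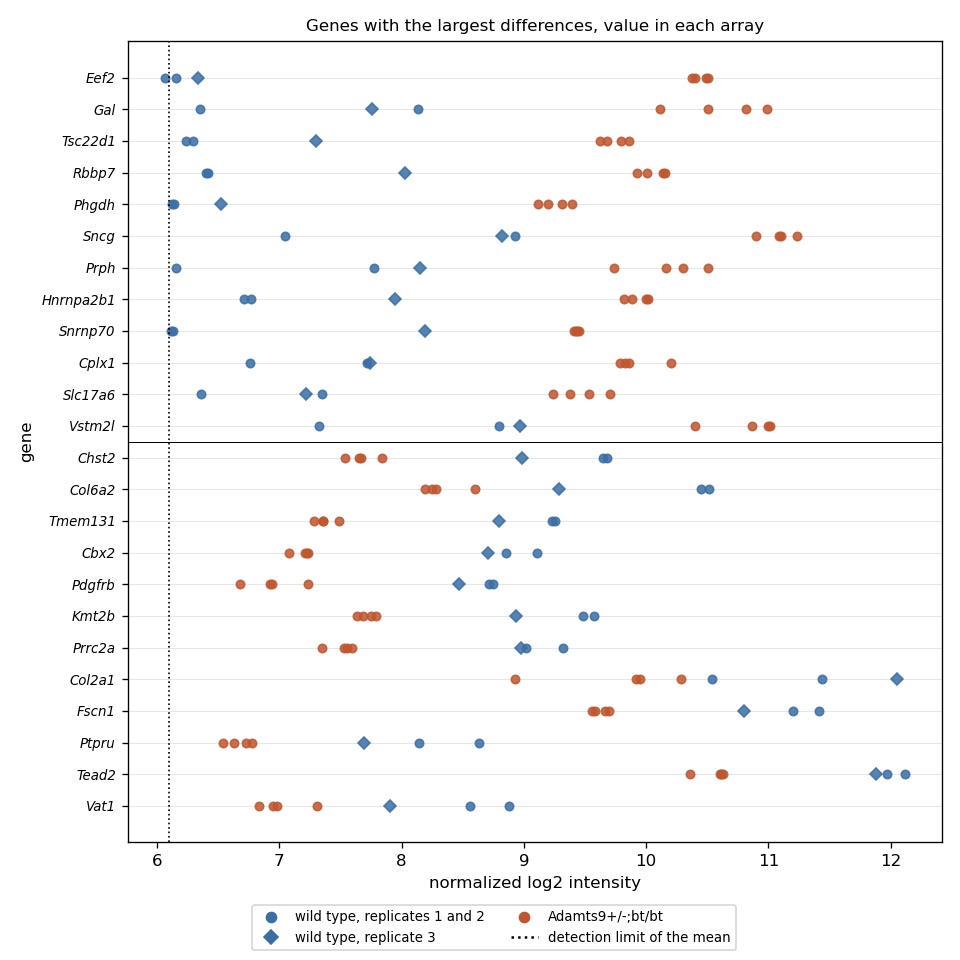
Normalized log2 intensity of the 12 named genes with the largest rises (upper part) and the 12 with the largest falls (lower part), each point 1 array; the dotted line is the detection limit for a gene's mean. Snrnp70, for example, lies at 6.13 and 6.12 in wild-type replicates 1 and 2, at 8.19 in replicate 3 and at 9.41 to 9.45 in the mutants.

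In all, 3995 of 10869 detected features passed an adjusted p of 0.05 by limma, 1840 higher and 2155 lower in the mutants. By gene this was 3720 of 10087, with 1724 higher and 1996 lower, of which 194 rose and 98 fell at least 2-fold and 28 rose and 0 fell at least 4-fold. Mutant and wild-type values did not overlap in 42.6% of features, where chance gives 5.71%. When arrays were centred on their medians in place of quantile normalization, the median of all features shifted by -0.14 and the split became 758 higher and 3875 lower, so the balance of the directions depended on the scaling. With wild-type replicate 3 as the only wild-type array, an alternative chosen after the data were seen, 1743 features passed, 750 higher and 993 lower.

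Neuron markers formed the gene list with the strongest shift. Of 22 detected neuron genes, 19 rose, 0 fell and 3 did not pass, and the same 19 to 0 split held when adjusted over the list alone. The median log2 difference was 1.45 (camera adjusted p = 5.77e-11; adjusted p = 0.654 with an estimated correlation). The transcription factors Isl1 (5.24-fold, log2 difference 2.39, SE 0.24) and Pou4f1 (log2 difference 1.43, SE 0.15, from a wild-type mean of 6.22 near the detection limit), which mark sensory neurons, rose, as did the RNA-binding protein Elavl2 (3.68-fold, SE 0.14), the microtubule protein Dcx (2.73-fold, SE 0.15) and the growth cone protein Gap43 (2.72-fold, SE 0.15), all with adjusted p at or under 0.000214. Tubb3 (log2 difference 0.10), Scg2 (0.08) and Ncam1 (0.05) did not pass. The mean over the list was 7.46, 6.74 and 7.38 in wild-type replicates 1 to 3 and 8.38, 8.70, 8.77 and 8.61 in the mutant arrays, so wild-type arrays also differed from each other in their neuron marker levels. Markers of neural crest glia, which accompany neurons in peripheral nerves and ganglia, moved less, with 2 of 6 detected genes higher, 1 lower and a median of 0.19 (camera adjusted p = 0.35). By fry, which sets a list against no change, the glia list was higher (adjusted p = 0.0128). Gfra3 rose by 0.58 (SE 0.15), Dhh rose by 0.23 (SE 0.05) and Cnp fell by 0.28 (SE 0.06), while Mbp (0.19, adjusted p = 0.0504) passed only when adjusted over the list alone, which made 3 higher.

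**Figure D2:**
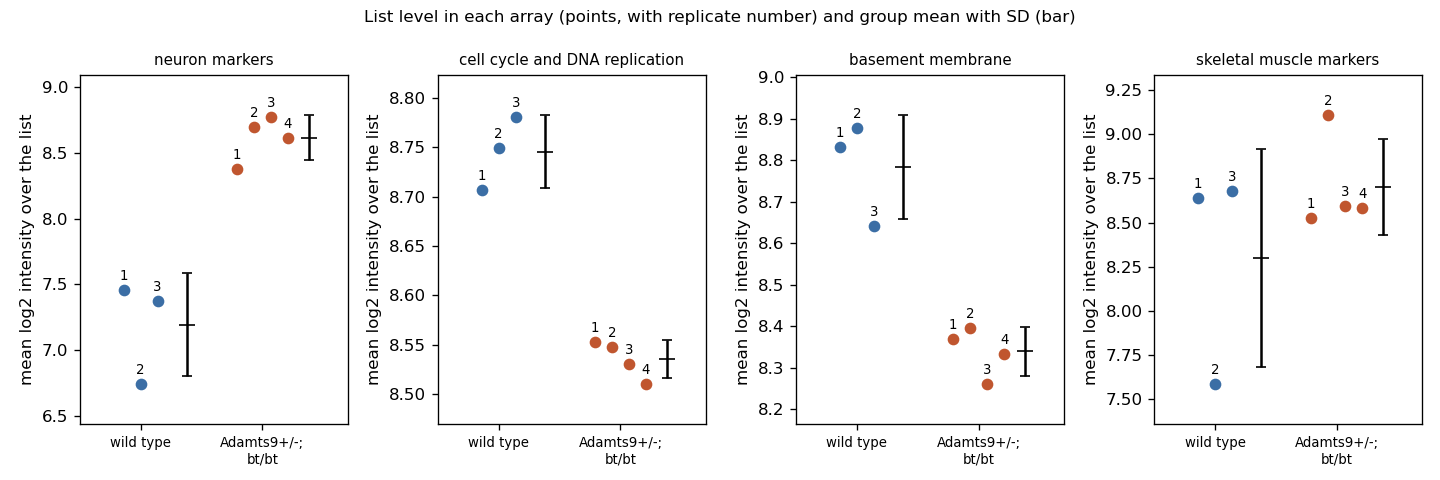
Mean normalized log2 intensity over the detected genes of 4 lists in each array (points, numbered by replicate), with each group's mean and SD (bar; n = 3 wild type, n = 4 mutant). The neuron list reads 6.74 to 7.46 in wild type and 8.38 to 8.77 in the mutants, the cell cycle list 8.71 to 8.78 and 8.51 to 8.55, and wild-type replicate 2 is the lowest array for both neuron and skeletal muscle markers.

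The cell cycle list, which bears on the proliferation named in the title, was lower in the mutants. Of 46 detected genes 26 fell, 3 rose and 17 did not pass, with the same counts adjusted over the list alone. The median log2 difference was -0.23 (camera adjusted p = 0.000123; adjusted p = 0.563 with an estimated correlation). With median centring it was -0.50, or -0.37 relative to the median of all features, and 35 genes fell. Among the genes that fell were the replicative helicase subunit Mcm2 (2.10-fold lower, log2 difference -1.07, SE 0.11, adjusted p = 0.00019), the phosphatase Cdc25a that drives entry into S phase (1.86-fold lower, SE 0.08), the spindle checkpoint kinase Bub1b (1.75-fold lower, SE 0.08), the mitotic kinesin Kif11 (1.64-fold lower, SE 0.08) and the G1 cyclin Ccnd2 (1.56-fold lower, SE 0.07). Mcm7, Ccne2 and Melk rose, Mcm7 by 2.32-fold (SE 0.09) from a wild-type mean of 6.30 near the detection limit. Every mutant array had a lower list mean (8.51 to 8.55) than every wild-type array (8.71 to 8.78). With wild-type replicate 3 as the only wild-type array, 15 list genes passed as lower and the list median was -0.22. With the mean of the neuron list as a covariate, the median was -0.11 (adjusted p = 0.0712) and 0 genes passed as lower. That covariate separates the groups without overlap, so this loss does not tell whether the cell cycle fall depends on the neuron genes. The list of CDK inhibitors and growth arrest genes had 7 of 15 detected genes higher, 1 lower and a median of 0.09 (camera adjusted p = 0.336), with the same counts adjusted over the list alone. It did not pass camera and was higher by fry (adjusted p = 0.0149). With median centring its median was -0.05, which lay 0.08 above the median of all features there. Cdkn1a, which encodes the CDK inhibitor p21, rose by 0.61 (SE 0.14), Cdkn1c, which encodes p57, by 0.42 (SE 0.09) and the retinoblastoma gene Rb1 by 0.65 (SE 0.08), while the p53 regulator Mdm2 fell by 0.31 (SE 0.05).

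Basement membrane genes were lower as a list, with 9 of 16 detected genes down, 0 up and a median of -0.36 (camera adjusted p = 0.00244; adjusted p = 0.654 with an estimated correlation), and 10 down adjusted over the list alone. The median was -0.54 with median centring, or -0.41 relative to the median of all features, and -0.24 with wild-type replicate 3 as the only wild-type array (adjusted p = 0.0217). With the mean of the neuron list as a covariate it was -0.19 (adjusted p = 0.295). Since that covariate separates the groups without overlap, this loss does not tell whether the fall depends on the neuron genes. The collagen IV genes Col4a2 (2.35-fold lower, SE 0.11) and Col4a1 (1.68-fold lower, SE 0.11), the laminin genes Lamb2 (1.92-fold lower, SE 0.11) and Lamb3 (1.98-fold lower, SE 0.13) and the nidogen gene Nid2 (1.86-fold lower, SE 0.14) fell, all with adjusted p at or under 0.00159. Endothelium markers, a cell type that lies on basement membrane, moved the same way without passing camera (adjusted p = 0.102). Of 19 detected genes 7 were lower and 0 higher, with a median of -0.17 and the same counts adjusted over the list alone. By fry the endothelium list was lower (adjusted p = 0.0248). The endothelial cadherin Cdh5 was 2.50-fold lower (SE 0.16), Eng 2.00-fold lower (SE 0.12) and Pecam1 1.73-fold lower (SE 0.09). The endothelium list passed camera without wild-type replicate 3 (-0.20, adjusted p = 0.0325) and without mutant replicate 1 (-0.18, adjusted p = 0.0269).

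**Figure D3:**
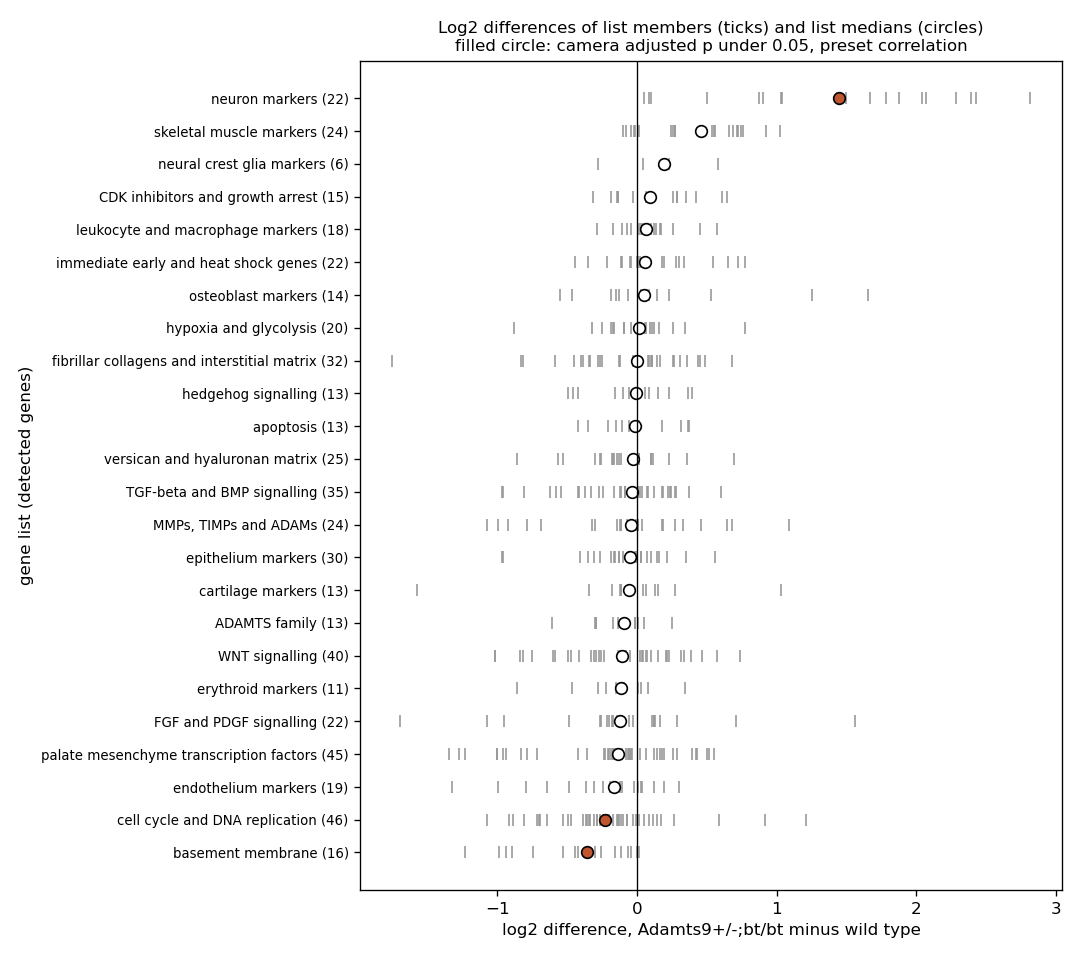
Log2 difference between mutant and wild type for every detected gene of the 24 lists tested (ticks) and each list's median (circles; filled where camera with the preset correlation passed). Neuron markers stand at a median of 1.45, cell cycle genes at -0.23 and basement membrane genes at -0.36, and the other medians lie between -0.17 and 0.46.

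No other matrix or protease list passed camera, which sets a list against other genes. By fry, which tests a list against no change, the versican and hyaluronan (adjusted p = 0.00624), ADAMTS (0.0116) and MMP, TIMP and ADAM lists (0.0339) were lower and the interstitial matrix list did not pass (0.738). The versican and hyaluronan list had 3 of 25 higher and 4 lower (median -0.03, camera adjusted p = 0.494), with the fibulins Fbln2 (-0.57, SE 0.06) and Fbln1 (-0.53, SE 0.10) and tenascin C (Tnc, -0.86, SE 0.12) lower and the neural proteoglycan Ncan higher (0.69, SE 0.14). In the ADAMTS family 1 of 13 was higher and 4 lower (median -0.09, camera adjusted p = 0.336), with 5 lower adjusted over the list alone, and Adamts7 showed the strongest fall (-0.61, SE 0.10, adjusted p = 0.00138). Among MMPs, TIMPs and ADAMs 4 of 24 were higher and 7 lower (median -0.04, camera adjusted p = 0.56). There the matrix protease genes Mmp2 (-0.79, SE 0.08) and Mmp11 (1.99-fold lower, SE 0.09), the inhibitor Timp2 (-1.07, SE 0.07) and the membrane-anchored inhibitor Reck (-0.93, SE 0.10) fell, and Adam23, which is known from neurons, rose (1.09, SE 0.10). Fibrillar collagens and interstitial matrix had 5 of 32 higher and 9 lower (median -0.0027, camera adjusted p = 0.885), 10 lower adjusted over the list alone, with Emilin1 (-0.83, SE 0.14) and the collagen cross-linking enzyme Plod2 (-0.59, SE 0.10) lower and Col3a1 higher (0.45, SE 0.09). The versican and hyaluronan list and the MMP, TIMP and ADAM list kept their counts adjusted over the list alone.

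Several well-known transcription factors and signalling genes of the palate fell, and their 5 lists did not pass camera. Over all genes 1724 of 10087 were higher and 1996 lower, so falls of single genes were common in this comparison. By fry the palate transcription factor (adjusted p = 0.00624), TGF-beta and BMP (0.00441), WNT (0.0116) and FGF and PDGF lists (0.0276) were lower and the hedgehog list did not pass (0.931). Palate mesenchyme transcription factors had 3 of 45 higher and 12 lower (median -0.14, camera adjusted p = 0.13), and 1 higher and 12 lower adjusted over the list alone. The list passed with wild-type replicate 3 as the only wild-type array (-0.12, adjusted p = 0.037). The mesenchymal genes Twist1 (2.35-fold lower, SE 0.09) and Tbx2 (2.55-fold lower, SE 0.10), the neural crest genes Dlx1 (1.64-fold lower, SE 0.09) and Dlx2 (1.73-fold lower, SE 0.09) and Sim2 (2.00-fold lower, SE 0.16) fell, and Zeb2 rose (1.41-fold, SE 0.06). In TGF-beta and BMP signalling 7 of 35 were higher and 10 lower (median -0.04, camera adjusted p = 0.494). Tgfb3, the ligand needed for fusion of the shelves, fell by 0.96 (SE 0.09, adjusted p = 0.00016), Fstl1 by 0.97 (SE 0.09) and Smad3 by 0.58 (SE 0.09), while Id4 rose by 0.60 (SE 0.09). WNT signalling had 5 of 40 higher and 12 lower (median -0.11, camera adjusted p = 0.33), with the receptors Fzd2 (-1.02, SE 0.11) and Fzd7 (-0.84, SE 0.10) lower. FGF and PDGF signalling had 3 of 22 higher and 6 lower (median -0.12, camera adjusted p = 0.494). Its FGF response genes Etv4 (-1.07, SE 0.14) and Etv5 (-0.95, SE 0.11) fell, and Fgf13, a neuronal member of the family, rose (1.56, SE 0.14). Hedgehog signalling had 2 of 13 higher and 3 lower (median -0.0067, camera adjusted p = 0.994 with an upward direction although median and mean lie below 0), with Shh (-0.49, SE 0.12) and Osr2 (-0.42, SE 0.10), a palatal growth gene, lower. In the TGF-beta, WNT, FGF and hedgehog lists the counts were the same adjusted over the list alone.

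Markers of the remaining cell types did not pass as lists. Skeletal muscle markers had a median of 0.46, with 1 of 24 higher (Des, 0.72, SE 0.23, adjusted p = 0.0359), 0 higher adjusted over the list alone and camera adjusted p = 0.13. Wild-type replicate 2 stood apart here at a list mean of 7.59, against 8.64 and 8.68 in the other wild-type arrays and 8.53 to 9.11 in the mutants. That list passed without wild-type replicate 1 (0.58, adjusted p = 0.0101), without wild-type replicate 3 (0.61, adjusted p = 0.0199) and with median centring (0.21, adjusted p = 0.00549). Without wild-type replicate 2 its median was 0.05 (adjusted p = 0.761). Epithelium markers had 2 of 30 higher and 4 lower (median -0.05, camera adjusted p = 0.494), with Cdh1 higher (0.56, SE 0.09) and Foxe1 lower (-0.97, SE 0.19), and 1 higher and 4 lower adjusted over the list alone. Cartilage markers had 0 of 13 higher and 1 lower, Col2a1 (median -0.05, camera adjusted p = 0.948). Osteoblast markers had 3 of 14 higher and 1 lower (median 0.05, camera adjusted p = 0.885), the bone matrix genes Ibsp (1.66, SE 0.30) and Ifitm5 (1.26, SE 0.32) being higher. With median centring the osteoblast median was -0.06, and with wild-type replicate 3 as the only wild-type array the list passed (0.18, adjusted p = 0.037). Erythroid markers had 1 of 11 higher and 2 lower (median -0.12, camera adjusted p = 0.494), with the embryonic globin Hba-x lower (-0.86, SE 0.15) and 0 higher and 1 lower adjusted over the list alone. Leukocyte and macrophage markers had 2 of 18 higher and 1 lower (median 0.06, camera adjusted p = 0.35), 2 higher and 0 lower adjusted over the list alone, with Coro1a (0.57, SE 0.10) and Lyz2 (0.45, SE 0.10) higher. Its median was -0.05 with median centring. The cartilage and osteoblast counts held adjusted over the list alone. Melanocyte markers, with 3 of 12 genes detected, and sex-linked genes, with 4 of 6, were too few for a list test. In them Ednrb, the endothelin receptor of neural crest lineages, rose by 0.89 (SE 0.11, adjusted p = 0.000454), and Xist (0.16, SE 0.72, adjusted p = 0.893) and Kdm5d (-0.19, SE 0.32, adjusted p = 0.70) did not pass.

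Lists of cell death and stress were mixed. Apoptosis genes had 2 of 13 higher and 3 lower (median -0.01, camera adjusted p = 0.948), with the p53 target Bbc3 higher (0.36, SE 0.06) and Casp8 (-0.42, SE 0.08) and Bcl2l11 (-0.35, SE 0.05) lower. Immediate early and heat shock genes had 6 of 22 higher and 2 lower (median 0.06, camera adjusted p = 0.33), among them the chaperones Hspa8 (0.72, SE 0.07) and Hspb1 (0.77, SE 0.14) and the immediate early gene Egr1 (0.66, SE 0.10). By fry this list was higher (adjusted p = 0.015), while the apoptosis (0.692) and hypoxia lists (0.939) did not pass. Hypoxia and glycolysis genes had 3 of 20 higher and 1 lower (median 0.02, mean -0.0098, median -0.25 with median centring, camera adjusted p = 0.994). The glycolytic enzyme genes Pkm (-0.88, SE 0.11) and Pfkp (0.78, SE 0.10) moved in opposite directions. Counts in these 3 lists were unchanged adjusted over the list alone.

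Both alleles can carry flanking DNA of the strain in which they arose, so genes near the targeted loci were set against the rest of the genome. The labels give the strain C57BL/6 for all samples, and the sources used here give no backcross history. Within 20 Mb of Adamts9 on chromosome 6, 48 of 124 detected genes passed the threshold (38.7%), against 36.8% of 9958 other genes (odds ratio 1.08, 95% interval 0.736 to 1.58, two-sided Fisher's exact p = 0.708, 0.708 after adjustment). Within 20 Mb of Adamts20 on chromosome 15 the count was 119 of 282 (42.2%), against 36.7% of 9800 others (odds ratio 1.26, 95% interval 0.981 to 1.61, Fisher's exact p = 0.0607, 0.121 after adjustment). Genes that fell made up 24.8% of that region against 19.6% elsewhere (odds ratio 1.35, 95% interval 1.01 to 1.79, Fisher's exact p = 0.0337, 0.0674 after adjustment), and the odds ratio for genes that rose was 1.02. Each adjustment covered only both loci within a kind of call (either direction, rises or falls), not all of these tests together. Prph and Col2a1, among the genes with the largest differences, lie in the Adamts20 region. The chromosome 15 region passed an unadjusted 0.05 by Fisher's exact test within 10 Mb (odds ratio 1.45, p = 0.036), without the detection filter (1.31, p = 0.0157) and when any of wild-type replicate 1 (1.39, p = 0.0103) or mutant replicates 2 (1.38, p = 0.0116), 3 (1.44, p = 0.00419) or 4 (1.33, p = 0.0239) was left out. The region also passed that limit with the replicate number as a block. It did not pass with the stricter filter (1.12, Fisher's exact p = 0.441), embryo sex as a covariate (1.19, p = 0.165), all probe IDs (1.19, p = 0.164), array weights (1.21, p = 0.128) or median centring (1.20, p = 0.127). Nor did it pass without background correction (1.25, Fisher's exact p = 0.0792), with the series table's log2 values (1.27, p = 0.0599) or with trend and robust eBayes (1.26, p = 0.0693). Leaving out wild-type replicate 2 (1.29, Fisher's exact p = 0.0509), wild-type replicate 3 (1.24, p = 0.074) or mutant replicate 1 (1.27, p = 0.0552) did not give a pass either. Near Adamts9 the odds ratio fell below 1 with the stricter detection filter (0.881, Fisher's exact p = 0.585) and with embryo sex as a covariate (0.991, Fisher's exact p = 1).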

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

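The tests of tissue carried along, of glia, of the differences among wild-type arrays in all features and in the RNA-binding genes, and of a sequence variant were chosen after the results were seen. The other tests were fixed beforehand.

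Among the 4 mutant arrays, 7 of 170 values tested had an array far from the other 3, where chance flags about 1 in 20 groups. Mutant replicate 3 was lowest for Cbx2 at 7.08 (the others 7.21 to 7.23), for Tead2 at 10.36 (10.60 to 10.63) and for Fzd7 at 8.48 (8.81 to 8.88). Mutant replicate 2 was highest for Wnt5b at 6.88 (6.78 to 6.79) and for the mean of the skeletal muscle list at 9.11 (8.53 to 8.59). Mutant replicate 4 was highest for Foxe1 at 8.14 (7.34 to 7.43), and mutant replicate 1 was lowest for Pth1r at 7.68 (7.93 to 7.98).

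The first pattern is the rise of neuron markers. Scaling between arrays was excluded as its whole cause, since without quantile normalization the neuron list median stayed at 1.27. Only the real one of the 35 splits of the arrays gave as many neuron genes higher (19, against at most 0 in the other splits). Chance assignment is thus unlikely but not excluded, as the smallest share that 35 splits can give is 2.86%. The real split also led for all features and for cell cycle genes, so this count is not particular to neuron genes. Nerve or ganglion tissue taken along in differing amounts may contribute but cannot be told apart from other shared variation of neuron genes. Wild-type replicate 2 was the lowest wild-type array for 21 of the 22 detected neuron genes, against 48.6% of all genes that rose. Any source that moves neuron genes together would give this, and the count compares wild-type arrays only. Whether nerve or ganglion tissue, if taken along, included its glia cannot be told apart, since the 6 detected glia genes went both ways (median 0.191, SD 0.279). As a list they did not pass camera (adjusted p = 0.35) and were higher by fry (adjusted p = 0.0128). A true gain of neurons or of their transcripts in the mutants stays open and was not tested.

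The second pattern is the group of 14 RNA-binding and translation factor genes that rose at least 2-fold, several of which, such as Eef2 and Snrnp70, lay near the detection limit in wild-type replicates 1 and 2. An RNA or labelling difference that also separates the wild-type arrays cannot be told apart from the genotype. Wild-type replicate 3 was the wild-type array nearest to the mutant mean in 13 of the 14, against 60.3% of all genes past the threshold, and since these genes share the same arrays the count carries no p. A sequence variant under the probe cannot be told apart either. In 6 members wild-type replicate 3 lay over 1 log2 unit above replicates 1 and 2, which a variant tied to the genotype would not give, but this rests on a single array and a variant that differs among wild-type embryos was not tested. The widest gap of the 6 was that of Eif3c, at 6.16 and 5.94 in wild-type replicates 1 and 2 and 9.12 in replicate 3. The mutants read 9.24 to 9.49, so for Eif3c most of the difference also lay within wild type. Of the other 8 members, 7 had replicate 3 above the mean of the other wild-type arrays, with a median gap of 0.26 over the 8. An effect of the genotype on these genes stays open and was not tested apart from the comparison itself.

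The third pattern is the large number of features past the threshold. Chance assignment is unlikely but not excluded, since only the real one of the 35 splits gave as many features (3995, against at most 4 in the others). The smallest share that 35 splits can give is 2.86%. The real split alone also gave as many cell cycle genes lower (26, against at most 0), which is not a separate test. The signal scale cannot be told apart from the genotype, since the upper quartiles of raw intensity (232.3 and 184) separate the groups. Mean raw intensities overlap, at 322.3 in wild-type replicate 3 and 323.4 in mutant replicate 1. The 4633 features that passed without quantile normalization do not decide it, because that setting leaves differences of scale in the values, and it moved the calls to 758 higher and 3875 lower. A difference between arrays other than genotype may contribute, because the difference of wild-type replicate 3 from replicates 1 and 2 correlated across features with the difference of the mutants from the remaining wild-type array (Pearson r 0.477 and 0.551, with no array shared; 0.20 for replicate 1 minus 2 against the mutants minus replicate 3). For the cell cycle genes that fell it cannot be told apart, as wild-type replicate 3 was the nearest wild-type array to the mutants in 12 of 26 (46.2%), against 60.3% of all genes past the threshold and 31.6% of the neuron genes that rose. By the mean over the whole cell cycle list, replicate 3 was the wild-type array farthest from the mutants. It read 8.78, against 8.71 and 8.75 in replicates 1 and 2 and 8.51 to 8.55 in the mutants, which rests on 1 array. Replicate 3 is also the only female wild-type embryo, and the part of embryo sex in the correlations above was not tested. With embryo sex as a covariate, 135 of 138 named genes kept their call. The genotype stays open as the source of the rest.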

How the results depend on the processing

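The settings that kept all probe IDs, used wild-type replicate 3 alone or added the neuron mean were chosen after the data were seen. The arrays' upper quartile of raw intensity, 232.3 in wild type and 184 in the mutants, against medians of 64.3 to 72.1 limits what dim genes such as Vcan and Adamts20 can show. Without background correction, with the series table's log2 values and with trend and robust eBayes, every count lay within 1.5 times and the neuron, cell cycle and basement membrane lists passed. With the preset correlation those 3 lists kept an adjusted p at or under 0.0217 in every setting but the neuron covariate. The cause was not tested for any change below unless stated. A block for the array chip was not run.

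With median centring, 758 features were higher and 3875 lower (16.4% higher), and sign changed for the lists of CDK inhibitors (-0.055), leukocytes (-0.052), osteoblasts (-0.061) and hypoxia (-0.25) and for Gadd45g (-0.055), Acvr2b (-0.0027) and Pfkl (-0.049). The median of all features shifted there by -0.14, and relative to it the neuron list stood at 1.41, the cell cycle list at -0.37 and the basement membrane list at -0.41. Requiring a log2 difference of at least 0.5 left 1365 features, 604 higher and 761 lower, as a stricter rule must. With all probe IDs as rows 6300 passed, 2884 higher and 3416 lower, because repeated values are counted again, and the hedgehog (0.048) and hypoxia (-0.00054) medians changed sign.

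With an estimated correlation 0 lists passed (neuron 1.45, cell cycle -0.23, basement membrane -0.36, adjusted p = 0.654, 0.563 and 0.654), and with fry, which does not compare a list with other genes, 14 passed. No detection filter turned the medians of apoptosis (0.0018), interstitial matrix (0.0078) and hedgehog (0.0035) and gave an odds ratio near Adamts20 of 1.31. The stricter filter turned cartilage (0.035) and the odds ratio near Adamts9 (0.881). Array weights turned apoptosis (0.012), hedgehog (0.00063), cartilage (0.036) and osteoblasts (-0.027). The mean of a gene's features turned hypoxia (-0.019). Embryo sex as a covariate turned interstitial matrix (0.025), Xist (-0.20) and the odds ratio near Adamts9 (0.991). The 10 Mb window gave 1.45 near Adamts20.

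Same-numbered arrays correlated at -0.199, -0.162 and 0.0645 in their deviations, which gave no clear sign that the replicate numbers pair the samples. No array of number 1 or 2 correlated best with its own number, while wild-type replicate 3 and mutant replicate 3, both from female embryos, did. Deviations within so few arrays cannot exclude a pairing. With the replicate block 2861 features passed, Vcan stood at 0.24 and was not past the threshold (adjusted p = 0.0508), the hypoxia median at -0.015 and the odds ratio near Adamts20 at 1.31 (Fisher's exact p = 0.0397).

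Leaving out each array in turn gave 2943 to 4315 features, 22 to 25 cell cycle genes lower, 19 neuron genes higher, 3 to 5 lists past the test, Vcan 0.19 to 0.28, Adamts20 -0.0092 to 0.056, odds ratios of 1.24 to 1.44 near Adamts20, and Xist -0.24 to 0.94. List medians that changed sign ran from -0.048 to 0.0039 (apoptosis), -0.058 to 0.12 (interstitial matrix), -0.057 to 0.051 (hedgehog), -0.18 to 0.18 (cartilage), -0.022 to 0.11 (osteoblasts) and -0.054 to 0.039 (hypoxia). Without wild-type replicate 3 the muscle and endothelium lists joined those past the test, making 5. Xist was high only in female embryos, so its values across these settings reflect which sexes were left in.

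With wild-type replicate 3 as the only wild-type array, assumed to vary like the mutants, 1743 features passed (750 higher, 993 lower), 5 lists passed (palate transcription factors and osteoblasts added), 15 cell cycle genes were lower and Vcan stood at 0.13. Sign changed for interstitial matrix (0.059), muscle (-0.018), hypoxia (-0.039), Kdm5d (0.41), Xist (-1.42) and Adamts5 (0.061). Replicate 3 is the only female wild-type embryo, so the changes of the sex-linked genes Xist and Kdm5d there follow embryo sex.

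The neuron mean separates the groups without overlap, so calls lost and signs changed with it as a covariate do not tell whether a difference follows it or the genotype. With that covariate 1 feature passed (1 higher, 0 lower, 100% higher), 0 cell cycle and 0 neuron genes passed and 1 list passed, muscle (-1.56). The medians became -0.11 for the cell cycle (adjusted p = 0.0712), -0.19 for basement membrane (adjusted p = 0.295) and 0.0057 for neurons. Sign changed for apoptosis (0.059), TGF-beta and BMP (0.017), hedgehog (0.0046), WNT (0.024), epithelium (0.0098), glia (-0.034), endothelium (0.056), osteoblasts (-0.16) and immediate early genes (-0.083). It also changed for Gal (-0.13), Sncg (-0.35), Prph (-0.63), Vstm2l (-0.55), Cdkn1c (-0.13), Cdkn1a (-0.42), Gadd45g (-0.11), Bcl2 (0.037), Ncan (-0.17), Vcan (-0.014), Adamts18 (0.071), Smad3 (0.017), Osr2 (0.0046), Shh (0.076), Grhl2 (0.32), Des (-0.91), Mbp (-0.11), Tal1 (0.056), Pfkl (-0.024), Kdm5d (0.36) and Xist (-0.67).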

Other observations

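Further groups of neuronal genes were chosen after the largest rises were known, which include Cplx1 and Slc17a6 of the synaptic group, and the groups were not tested against each other. All 14 detected genes of synaptic vesicles and release rose, with a median log2 difference of 1.33. Among them Rims3, a scaffold of the release site, read 10.14 in 4 mutants against 7.96 in 3 wild types (adjusted p = 0.000246), and Svop, a vesicle transporter, 9.05 against 7.11 (adjusted p = 0.000186). Of 11 detected genes of sensory ganglion neurons 6 rose and 0 fell, with a median of 1.18. Pirt, a regulator of sensory ion channels, read 8.39 against 6.43 (adjusted p = 0.000123), the purinergic receptor P2rx3 7.88 against 6.50 (adjusted p = 0.000198) and the sensory sodium channel Scn10a 7.32 against 6.14 (adjusted p = 0.000344). The wild-type mean of Scn10a lies near the detection limit, so the size of its difference depends on the floor. Of 7 detected genes of autonomic neurons 2 rose, Th (2.47-fold, adjusted p = 0.000226) and Npy, and 5 did not pass (median 0.06), and of 4 detected genes of central nervous system progenitors Sox2 rose and Nes fell (median 0.12). With median centring the synaptic and sensory medians were 1.09 and 1.08, with 1 sensory gene lower, and the autonomic median was -0.12.

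Families of widely expressed genes were also counted after the data were seen, and their balance depended on the scaling. Of 118 detected genes of RNA-binding proteins and translation factors 29 were higher and 30 lower (median -0.03), yet 14 of them rose at least 2-fold, 11.9% against 1.92% of all detected genes, and 2 fell as far. With median centring 18 were higher and 60 lower (median -0.25, which is 0.11 under that of all features), and 14 again rose at least 2-fold. Cytoplasmic ribosomal protein genes, 62 of them detected, had 4 higher, 2 lower and a median of 0.01, and with median centring 1 was higher and 17 lower, with a median of -0.13 close to that of all features (-0.14).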
